A study of Homo sapiens with 42 samples.

How the data were processed

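RNA-seq libraries of prostate cancer cells were analysed from 6 tables of gene counts, 42 libraries in 14 groups of 3. Per the labels' protocols, total RNA was purified with a column kit and made into libraries with a directional kit, from cells grown in RPMI with serum. The counts deposited by the authors are whole numbers of reads per gene, not normalized, as the values show, although 4 of the tables are named as FPKM in their file names. Per the submitters' processing notes, Trim Galore, HISAT2 and featureCounts were used for the C4-2 samples and hg38 was the build for all, with no versions or roles given. For the 22RV1 tables the aligner and counter are not given in the sources used here, nor is the strand setting of any count, so antisense and overlapping genes are uncertain. The design foresaw limma on log2 FPKM for the 4 tables and edgeR on them if they proved to hold counts, so edgeR was used.

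Groups and replicate numbers were taken from the sample titles. The titles were followed for the RB(245-255) plasmid libraries, where a genotype field names the control group, and for a PROTAC library whose cell line field reads differently from its group. Columns were matched to samples by name, and 0 columns were left without a sample. Tables were tested separately, because they were counted separately. Genes were matched to GENCODE 29 (GRCh38) by symbol or Ensembl ID, which covered 64.7% to 96.9% of the entries of a table and 99.1% to 99.8% of its reads. Genes with a repeated name, and genes on alternate contigs, are not named in the text. Named genes were not screened by sequence for near-identical copies elsewhere in the genome, so reads shared with such copies are uncertain.

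Counts were filtered with filterByExpr (minimum count 10, minimum total 15), scaled by TMM and tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) with Benjamini-Hochberg adjustment over all tested genes, at an adjusted p under 0.05. Comparisons within the siRNA table of 22RV1 and the PROTAC table used all 9 libraries for the spread, and the others their 6 libraries. An SE is the absolute log2 fold change divided by the square root of the F statistic. Levels are TMM-scaled CPM, except those that set cell lines side by side, which are plain CPM. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

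The comparisons, the tests, 26 gene lists and the rule for named genes were fixed before the data were examined. The lists cover E2F targets, G2 and mitosis, androgen receptor targets, luminal, basal, neuroendocrine, fibroblast and leukocyte markers, ATF4 targets downstream of mTORC1, the mTOR pathway, SREBP targets, HIF and glycolysis genes, the unfolded protein response, heat shock, NRF2, p53, NF-kB and interferon targets, MAPK feedback and immediate early genes, dual-specificity phosphatases, retinoic acid targets, ribosomal proteins, the proteasome, nuclear-encoded and mitochondrial subunits of respiration and nuclear-retained transcripts. Lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, with adjusted p over the lists, and again with a correlation estimated per list. The rule named TRIM24, RB1 and DUSP2, the 6 largest rises and 6 largest falls among called protein-coding genes with groups that do not overlap and at least 5 CPM in the higher group, and up to 3 members of each list that was called or had at least 3 called members. For length, not all are in the text, and a few genes are not reported here. Most genes whose call was lost under an alternative were left out by choice, after their values were seen. The genes in the text and in the closing counts are thus steadier than the rule's whole set.

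Replicates were compared by a chi-square test over genes with at least 20 reads. The lowest chi-square per degree of freedom was 1.39, so no libraries were taken as copies. Overlaps of called genes were tested with Fisher's exact test. For comparisons with shared controls, unchanged groups were simulated 20 times. Length and GC content came from the annotated transcripts of GENCODE 29, and a trend over both (splines with 5 degrees of freedom) was fitted per library and removed as an offset. That offset was chosen after the data were seen and centred after a first version without centring was seen to shift the scale. All other alternatives are named in the closing section.

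The test was checked on counts simulated from the real means and library sizes with 200 genes changed. With each gene's own dispersion, which was simulated first, false calls made up 9.14% (siRB1, 17237 genes), 10.05% (RB(245-255), 17194 genes), 10.87% (PROTAC 10, 19698 genes) and 10.85% (C4-2 RB1, 15544 genes) of calls, above the nominal 5%. With dispersions on the trend over expression, simulated after that was seen, they were 4.35%, 3.66%, 5.71% and 3.94%. At folds of 1.5, 2 and 4 and each gene's own dispersion, 65.7%, 83.6% and 97% of changed genes were recovered for siRB1, 61.2%, 89.6% and 97% for RB(245-255), 56.7%, 74.6% and 97% for PROTAC 10 and 74.6%, 86.6% and 97% for C4-2 RB1.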

Results

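Total RNA was sequenced from prostate cancer cell lines in 42 libraries, which the labels place in 14 groups of 3. The label 22RV1 names a line grown from a prostate cancer xenograft, and C4-2 is a line derived from LNCaP prostate cancer cells. In the siRNA experiment labelled 22RV1, groups treated with siRNA against TRIM24 (siTRIM24) or RB1 (siRB1) shared 1 control group (siNC). Further libraries labelled 22RV1 carried plasmids for RBN or for residues 245 to 255 of RB, both tagged HA, although the design text begins the range 1 residue earlier. Each plasmid had a group labelled EV as control. Others received an RB PROTAC at 0, 5 or 10 µmol/L. A PROTAC is a small molecule that brings a protein to the cell's degradation machinery. In C4-2, RB1 and TRIM24 knockdowns each had their own control group. RB1 encodes the retinoblastoma protein, a repressor of cell cycle genes. TRIM24 encodes a chromatin-binding coactivator of nuclear receptors, and DUSP2 encodes a nuclear phosphatase of MAP kinases. The series title places these genes in 1 question, the action of RB and TRIM24 on mTOR signalling through DUSP2.

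The total count per library was 15908745 to 17670961 in the siRNA table of 22RV1, 15688628 to 17832954 in the RBN table and 16298787 to 39983915 in the RB(245-255) table. It was 9505662 to 46180041 in the PROTAC table, where the shallowest library was replicate 1 at 0 µmol/L. In the C4-2 tables it was 13697094 to 17511309 for RB1 and 26012815 to 31543374 for TRIM24. The 13 messenger RNAs of the mitochondrial genome had no count in 5 of the 6 tables, and mitochondrial transcripts took 5.43% to 7.04% of the counts in the siRNA table of 22RV1. Nothing in the labels states that libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. Values below are log2 fold changes ± SE and TMM-scaled CPM ± SD, with n = 3 per group, and adjusted p from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

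The targets are given first. On hg38, TRIM24 (ENSG00000122779) lies on chromosome 7 from 138460334 to 138589993 on the plus strand. RB1 (ENSG00000139687) lies on chromosome 13 from 48303726 to 48599436 on the plus strand, and DUSP2 (ENSG00000158050) on chromosome 2 from 96143166 to 96145440 on the minus strand. TRIM24 fell in siTRIM24 libraries of 22RV1, from 170.3 ± 3.66 to 115 ± 1.73 CPM, and RB1 fell in siRB1 libraries, from 155 ± 7.49 to 80.7 ± 3.96 CPM. RB1 also fell in the C4-2 RB1 knockdown, from 79.1 ± 4.04 to 60.9 ± 4.64 CPM. The C4-2 libraries labelled trim24si went against their label, with TRIM24 at 104 ± 1.61 CPM against 77.8 ± 2.19 in the libraries labelled trim24nc, and every library of the first group lay above every library of the second. RB1 counts rose with the RBN plasmid, from 49 ± 2.23 to 78.2 ± 1.83 CPM, and did not change detectably with the RB(245-255) plasmid, at 101 ± 4.33 and 93.6 ± 3.66 CPM. RB1 messenger RNA was 77.3 ± 1.1 CPM without PROTAC and 63.5 ± 2.97 CPM at 10 µmol/L, although a PROTAC acts on protein.

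**Figure D1:**
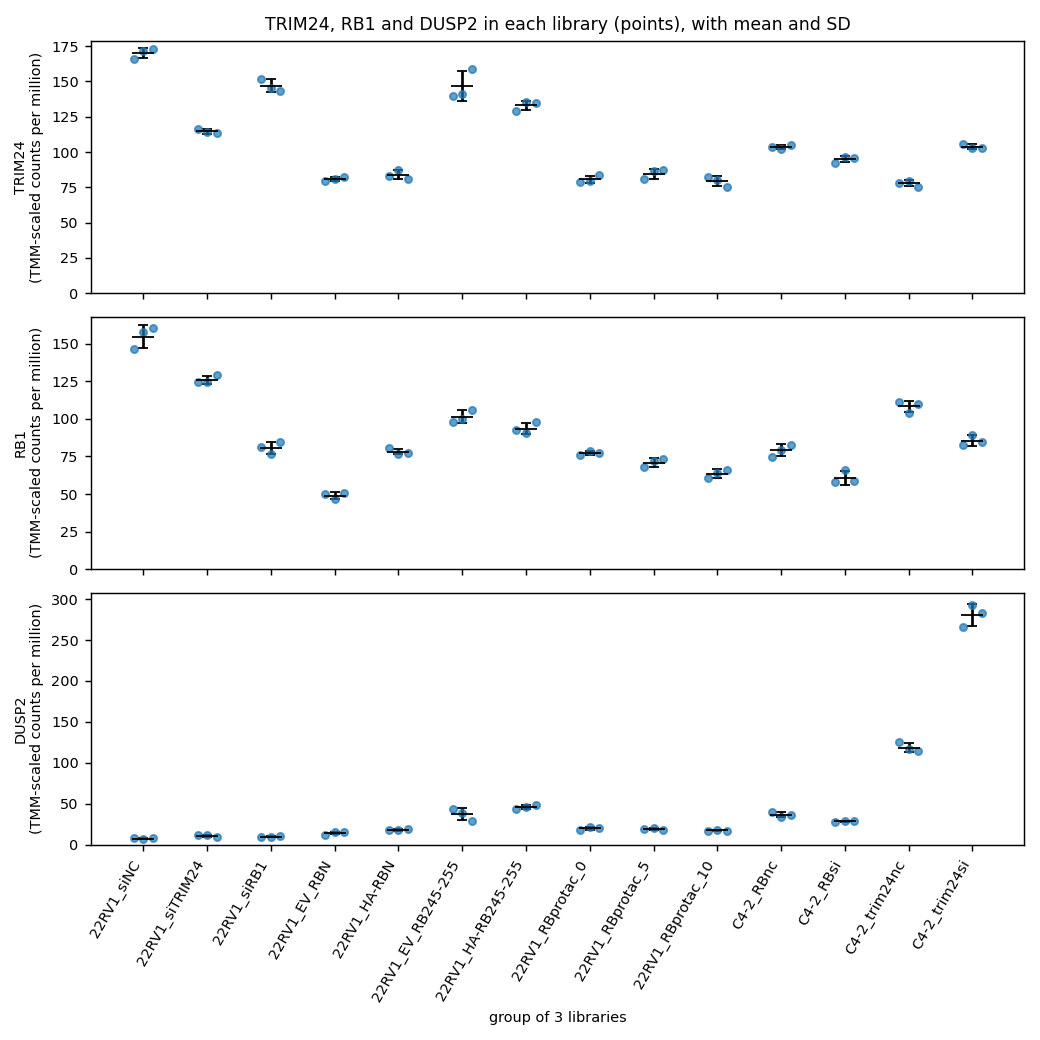
TMM-scaled CPM of TRIM24, RB1 and DUSP2 (vertical axes) in each of the 14 groups of 3 libraries (horizontal axis), with points for libraries and bars for mean and SD. TRIM24 is higher in the C4-2 libraries labelled trim24si (104 CPM) than in their controls (77.8 CPM), and DUSP2 is highest in the libraries labelled trim24si (281 CPM), although the tables were counted and scaled separately.

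The libraries labelled 22RV1 fell into sets of different make-up, a comparison chosen after the values were seen. Of 199 genes at 10 CPM or more in the 22RV1 siNC libraries and under 0.1 CPM in the C4-2 RB1 control libraries, RBN libraries detected 3.0% to 4.5% at 1 CPM or more and PROTAC libraries 2.0% to 4.0%. The RB(245-255) libraries detected 66.3% to 67.3% of them. Of 45 genes with the opposite pattern, RBN and PROTAC libraries both detected 95.6% to 97.8%, and RB(245-255) libraries 15.6% to 20%. KLK3, which encodes prostate-specific antigen, stood at 4.52 ± 1.23 CPM in siNC and 10.5 ± 1.69 CPM in the EV libraries of RB(245-255), against 2568 ± 31.2 CPM in the EV libraries of RBN, 2713 ± 47.0 CPM in the PROTAC libraries at 0 µmol/L and 3038 ± 94.4 CPM in the C4-2 RB1 controls. These levels come from tables that were counted and scaled separately. All tests below were made within a table, and RBN and PROTAC libraries are called labelled 22RV1.

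**Figure D2:**
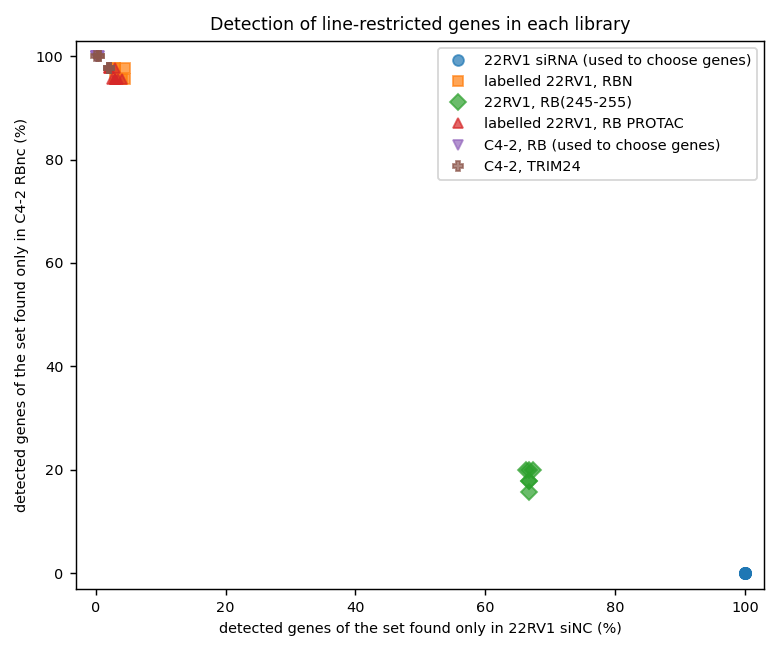
Percent of the 199 genes found only in the 22RV1 siRNA controls (horizontal axis) against percent of the 45 genes found only in the C4-2 RB1 controls (vertical axis) detected in each library, with 1 point per library and the tables by symbol. RBN and PROTAC libraries lie beside C4-2 libraries, at 2.0% to 4.5% on the horizontal axis.

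With siTRIM24 in 22RV1, nuclear-encoded respiratory chain and ribosomal protein genes were higher as lists, and mitochondrial transcripts, mitotic genes and amino acid metabolism genes were lower. Of the 7 lists called, 0 were called with an estimated correlation (adjusted p = 0.55 to 0.74). MRPL12, a mitochondrial ribosomal protein, rose by 1.17 ± 0.114, PSENEN, a subunit of gamma-secretase, by 1.17 ± 0.14, and TAF10, a subunit of the general transcription factor TFIID, by 1.0 ± 0.11. TMEM256 rose by 1.03 ± 0.134. The zinc finger gene ZNF460 changed by -0.80 ± 0.121. TRIM24 itself changed by -0.57 ± 0.043 (adjusted p = 1.2e-08), RB1 by -0.30 ± 0.048 (adjusted p = 1.0e-04) and DUSP2 by 0.52 ± 0.118 (adjusted p = 0.0025), from 7.84 ± 0.396 to 11.2 ± 1.02 CPM.

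Of the nuclear-encoded subunits of the respiratory chain, 21 of 58 rose, 3 fell and 34 did not pass. 25 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 6.6e-04 and adjusted p = 0.55 with an estimated correlation. Examples were COX8A (0.63 ± 0.066) and COX6A1 (0.64 ± 0.068) of cytochrome c oxidase and NDUFA1 of complex I (0.54 ± 0.061). Among cytosolic ribosomal proteins 31 of 73 rose, 5 fell and 37 did not pass. 32 rose and 6 fell when adjusted over the list alone, and the list had adjusted p = 8.8e-04 and adjusted p = 0.74 with an estimated correlation. RPL36 and RPL26 changed by 0.54 ± 0.052 and 0.81 ± 0.094. Of messenger RNAs encoded in mitochondria 9 of 13 fell, 0 rose and 4 did not pass. 10 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 1.1e-04 and adjusted p = 0.55 with an estimated correlation. Among them were MT-CO1 (-0.31 ± 0.026) and MT-CO2 (-0.39 ± 0.038). The list of HIF targets and glycolytic enzymes moved up, where 14 of 30 rose, 2 fell and 14 did not pass. 14 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 0.02 and adjusted p = 0.64 with an estimated correlation. NDRG1, a hypoxia-induced gene, rose by 0.31 ± 0.046, VEGFA, the vascular growth factor, by 0.27 ± 0.043 and PFKFB3, which stimulates glycolysis, by 0.34 ± 0.054.

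Genes of G2 and mitosis moved down, where 18 of 40 fell, 1 rose and 21 did not pass. 22 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 8.8e-04 and adjusted p = 0.55 with an estimated correlation. The spindle checkpoint kinase TTK changed by -0.32 ± 0.065 and the centrosomal kinase NEK2 by -0.24 ± 0.048. Of ATF4 targets of amino acid and one-carbon metabolism 14 of 39 fell, 3 rose and 22 did not pass. 16 fell and 3 rose when adjusted over the list alone, and the list had adjusted p = 0.0037 and adjusted p = 0.55 with an estimated correlation. Examples were the glycyl-tRNA synthetase GARS1 (-0.29 ± 0.037) and the mitochondrial folate enzyme ALDH1L2 (-0.32 ± 0.046). Of nuclear-retained transcripts, a sign of RNA composition, 5 of 9 fell, 1 rose and 3 did not pass. 6 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 0.048 and adjusted p = 0.64 with an estimated correlation.

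In all, 3939 of 17237 tested genes passed with siTRIM24, 2209 up and 1730 down, and 76 of them exceeded an absolute log2 fold change of 1. Fold changes moved with transcript GC content (Spearman rho 0.575 across genes, which are not independent replicates). The median GC content was 60.3% in risen and 42.1% in fallen genes. With a trend over GC content and length removed, chosen after seeing the data, 574 rose and 670 fell. Of these 1244 genes, 860 had passed before. DUSP2 was then 0.27 (adjusted p = 0.17), the G2 and mitosis list had adjusted p = 0.12 and the nuclear-retained list adjusted p = 0.30. Of the HIF and glycolysis list 6 of 30 then rose, with a median of 0.041 in place of 0.109 (adjusted p = 0.025). In the same fit 22 of 39 ATF4 targets fell, with adjusted p = 0.023 with an estimated correlation. Of the values given, those of RB1 (-0.18), RPL36 (0.29), NDRG1 (0.14), VEGFA (0.13), PFKFB3 (0.14), TTK (-0.20), NEK2 (-0.13) and ALDH1L2 (-0.21) moved by over 1.5 times with the trend removed and still passed. The count was 2339 without siNC replicate 2, 2593 without siNC replicate 3 and 2517 without siTRIM24 replicate 2.

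**Figure D3:**
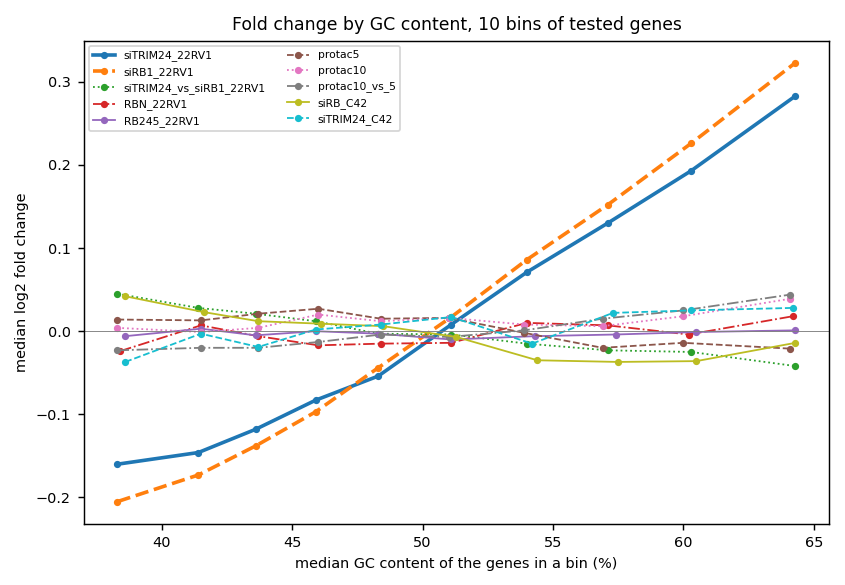
Median log2 fold change (vertical axis) of tested genes in 10 bins of transcript GC content in percent (horizontal axis), with 1 line per comparison. The siTRIM24 and siRB1 lines of 22RV1 climb with GC content (Spearman rho 0.575 and 0.613 across genes), while those of the 7 comparisons other than these and their direct contrast have a rho between -0.105 and 0.135.

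With siRB1 in 22RV1, glycolytic and hypoxia genes were higher and genes of amino acid metabolism and mitosis were lower. Of the 6 lists called, 0 were called with an estimated correlation (adjusted p = 0.15 to 0.51). RB1 changed by -0.94 ± 0.049 (adjusted p = 2.7e-12). Of the ATF4 targets 29 of 39 fell, 2 rose and 8 did not pass. 31 fell and 4 rose when adjusted over the list alone, and the list had adjusted p = 1.3e-10 and adjusted p = 0.15 with an estimated correlation. The cystine transporter SLC7A11 changed by -0.73 ± 0.057, ALDH1L2 by -0.57 ± 0.046 and GARS1 by -0.45 ± 0.037. Of HIF targets and glycolytic enzymes 21 of 30 rose, 0 fell and 9 did not pass. 22 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 3.4e-07 and adjusted p = 0.25 with an estimated correlation. NDRG1 rose by 0.60 ± 0.046, PFKFB3 by 0.51 ± 0.054 and the glycolytic enzyme TPI1 by 0.25 ± 0.033.

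Among called protein-coding genes at 5 CPM or more, large rises were those of TMEM256 (1.32 ± 0.131), TAF10 (1.17 ± 0.108), PSENEN (1.16 ± 0.14), MRPL12 (1.08 ± 0.114) and RALGDS, an exchange factor of Ral GTPases (1.04 ± 0.128). Of genes of G2 and mitosis 22 of 40 fell, 0 rose and 18 did not pass. 24 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 3.2e-05 and adjusted p = 0.25 with an estimated correlation. The kinesin CENPE changed by -0.43 ± 0.079. The E2F list was not called as a whole (adjusted p = 0.27), and 16 of 52 fell, 12 rose and 24 did not pass (20 fell and 13 rose when adjusted over the list alone), with RRM2, a subunit of ribonucleotide reductase, at -0.29 ± 0.044 and DTL, a substrate receptor of a ubiquitin ligase, at -0.30 ± 0.045. Of nuclear-encoded respiratory chain subunits 18 of 58 rose, 3 fell and 37 did not pass. 18 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 0.0036 and adjusted p = 0.5 with an estimated correlation. Of ribosomal proteins 34 of 73 rose, 5 fell and 34 did not pass. 37 rose and 5 fell when adjusted over the list alone, and the list had adjusted p = 5.0e-05 and adjusted p = 0.51 with an estimated correlation. COX8A changed by 0.66 ± 0.066 and RPL36 by 0.55 ± 0.052. Of mitochondrial messenger RNAs 10 of 13 fell, 0 rose and 3 did not pass. 11 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 3.7e-05 and adjusted p = 0.5 with an estimated correlation. MT-CO1 changed by -0.38 ± 0.026. Of nuclear-retained transcripts, not called as a list (adjusted p = 0.05), 4 of 9 fell, 1 rose and 4 did not pass (4 fell and 1 rose when adjusted over the list alone). FASN, the fatty acid synthase, rose by 0.51 ± 0.048.

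In total 5194 of 17237 genes passed with siRB1, 2764 up and 2430 down, with 105 above an absolute log2 fold change of 1. Their fold changes also moved with GC content (rho 0.613 across genes, medians of 60% in risen and 42.1% in fallen genes). With the trend removed 879 rose and 927 fell. Of these 1806, 1280 had passed before, 1251 in the same direction. Then 34 of 39 ATF4 targets fell and 16 of 30 HIF and glycolysis genes rose (estimated correlation, adjusted p = 0.0025 and 0.042). Of the G2 and mitosis list 6 of 40 then fell, with a median of -0.048 in place of -0.135 (adjusted p = 0.0082), and the median of ribosomal proteins was 0.059 in place of 0.112. PFKFB3 was then 0.27, TPI1 0.12, CENPE -0.19, DTL -0.15, RPL36 0.25 and FASN 0.15, moved by over 1.5 times and still past the test. TRIM24 was -0.21 ± 0.043 (adjusted p = 4.9e-04) and, with the trend removed, -0.10 (adjusted p = 0.069). DUSP2 was 0.34 ± 0.119 (adjusted p = 0.032) and did not pass with the trend removed (0.07, adjusted p = 0.80), with no filter on low counts (adjusted p = 0.075), or without siNC replicate 2 (adjusted p = 0.12), siNC replicate 3 (adjusted p = 0.07), siRB1 replicate 2 (adjusted p = 0.091) or siRB1 replicate 3 (adjusted p = 0.13).

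Set directly against siRB1, siTRIM24 libraries had higher ATF4 targets, a contrast with no control library in the difference. RB1 differed by 0.64 ± 0.05 and TRIM24 by -0.36 ± 0.043, while DUSP2 differed by 0.18 ± 0.114 (adjusted p = 0.78). Of ATF4 targets 10 of 39 rose, 0 fell and 29 did not pass. 29 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 5.0e-21 and adjusted p = 0.027 with an estimated correlation. SLC7A11 differed by 0.49 ± 0.057, SESN2, an inhibitor of mTORC1 signalling induced by amino acid shortage, by 0.35 ± 0.049 and PSAT1, of serine synthesis, by 0.24 ± 0.038. SESN3, of the same family as SESN2, differed by 0.45 ± 0.058. Of the HIF and glycolysis list 3 of 30 fell, 0 rose and 27 did not pass. 13 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 1.2e-11 and adjusted p = 0.089 with an estimated correlation. Members included LDHA, lactate dehydrogenase (-0.22 ± 0.032), and NDRG1 (-0.29 ± 0.046). Of luminal markers 2 of 14 fell, 0 rose and 12 did not pass. 5 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 0.0011 and adjusted p = 0.21 with an estimated correlation. Among them was keratin KRT19 (-0.36 ± 0.059). The intermediate filament gene VIM differed by -0.38 ± 0.064.

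Of androgen receptor targets 4 of 32 fell, 0 rose and 28 did not pass. 7 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 0.0035 and adjusted p = 0.21 with an estimated correlation. The lists of G2 and mitosis (adjusted p = 0.038, and adjusted p = 0.50 with an estimated correlation), ribosomal proteins (adjusted p = 0.049, and adjusted p = 0.77) and SREBP targets (adjusted p = 0.038, and adjusted p = 0.46) passed the list test with 0 members past the gene test, also when adjusted over the list alone. With the GC and length trend removed the G2 and mitosis (adjusted p = 0.29) and ribosomal (adjusted p = 0.2) lists were not called, nor was the ribosomal list with RLE size factors (adjusted p = 0.056). In this contrast 54 genes passed, 28 up and 26 down, and 1316 had an unadjusted p under 0.05. The count was 27 without siRB1 replicate 2, 35 without siRB1 replicate 3, 32 without siTRIM24 replicate 1, 95 with DESeq2, 131 with no filter on low counts and 130 with the GC and length trend removed. Called lists numbered 7, and 4 without siRB1 replicate 3, 4 without siTRIM24 replicate 1 and 3 without siTRIM24 replicate 3.

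With the RBN plasmid, in libraries labelled 22RV1, cell cycle and interferon genes were higher, and androgen receptor, sterol synthesis and unfolded protein response genes were lower. All 53 tested E2F targets of DNA replication rose (53 also when adjusted over the list alone), with adjusted p = 2.5e-26 and adjusted p = 0.0038 with an estimated correlation, including RRM2 (2.95 ± 0.042) and the replicative helicase subunits MCM4 (2.25 ± 0.043) and MCM7 (1.5 ± 0.03). All 39 genes of G2 and mitosis rose (39 also when adjusted over the list alone), with adjusted p = 1.7e-18 and adjusted p = 0.0096 with an estimated correlation, such as the mitotic kinase CDK1 (1.65 ± 0.028), the proliferation marker MKI67 (1.32 ± 0.034) and TOP2A, a DNA topoisomerase (1.16 ± 0.031). RB1 counts were 0.68 ± 0.048 (adjusted p = 1.4e-13), DUSP2 was 0.36 ± 0.096 (adjusted p = 0.0021) and TRIM24 was 0.05 ± 0.041 (adjusted p = 0.31), and 0.024 without HA-RBN replicate 2.

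Of interferon-stimulated genes 35 of 37 rose, 2 fell and 0 did not pass. 35 rose and 2 fell when adjusted over the list alone, and the list had adjusted p = 1.7e-18 and adjusted p = 0.0038 with an estimated correlation. IFIT1 and IFIT2, which bind foreign RNA, rose by 3.79 ± 0.034 and 3.38 ± 0.033, OAS2 and OAS3, which activate RNase L, by 4.84 ± 0.078 and 3.55 ± 0.037, IFI44L by 5.17 ± 0.122 and XAF1, a proapoptotic gene, by 5.42 ± 0.231. PLD1, a phospholipase, reached 8.51 ± 0.479 CPM from 0.191 ± 0.119. Of androgen receptor targets 32 of 34 fell, 1 rose and 1 did not pass. 32 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 2.5e-18 and adjusted p = 0.0038 with an estimated correlation. FKBP5, a cochaperone, went from 1921 ± 22.9 to 136 ± 3.78 CPM (-3.82 ± 0.026), SLC45A3 changed by -4.45 ± 0.031 and PMEPA1 by -3.42 ± 0.031. The metalloreductase STEAP4 changed by -6.54 ± 0.156, the amino acid transporter SLC38A4 by -7.27 ± 0.282 and the transcription factor SNAI2 by -5.25 ± 0.139.

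Of SREBP targets of sterol and fatty acid synthesis 26 of 31 fell, 2 rose and 3 did not pass. 26 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 7.9e-10 and adjusted p = 0.018 with an estimated correlation. FASN changed by -2.26 ± 0.024, the desaturase SCD by -1.27 ± 0.02 and squalene synthase FDFT1 by -1.52 ± 0.026. Of unfolded protein response genes 22 of 23 fell, 0 rose and 1 did not pass. 22 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 2.0e-09 and adjusted p = 0.011 with an estimated correlation. Examples were the chaperone HSPA5 (-0.77 ± 0.023) and the sensor ERN1 (-1.57 ± 0.048). Of the dual-specificity phosphatases, not called as a list (adjusted p = 0.51), 7 of 18 fell, 4 rose and 7 did not pass (7 fell and 4 rose when adjusted over the list alone). Heat shock genes, nuclear-encoded respiratory subunits and proteasome subunits were higher as lists. Of heat shock genes 13 of 18 rose, 2 fell and 3 did not pass. 13 rose and 2 fell when adjusted over the list alone, and the list had adjusted p = 0.0039 and adjusted p = 0.087 with an estimated correlation. Of respiratory subunits 25 of 57 rose, 3 fell and 29 did not pass. 25 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 0.0039 and adjusted p = 0.4 with an estimated correlation. Of proteasome subunits 16 of 30 rose, 4 fell and 10 did not pass. 17 rose and 4 fell when adjusted over the list alone, and the list had adjusted p = 0.048 and adjusted p = 0.22 with an estimated correlation. ATF4 targets, NRF2 targets and nuclear-retained transcripts were lower as lists. Of ATF4 targets 23 of 39 fell, 9 rose and 7 did not pass. 23 fell and 9 rose when adjusted over the list alone, and the list had adjusted p = 0.0039 and adjusted p = 0.14 with an estimated correlation. Of NRF2 targets 13 of 21 fell, 4 rose and 4 did not pass. 13 fell and 4 rose when adjusted over the list alone, and the list had adjusted p = 0.012 and adjusted p = 0.11 with an estimated correlation. Of nuclear-retained transcripts 6 of 9 fell, 1 rose and 2 did not pass. 6 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 0.033 and adjusted p = 0.19 with an estimated correlation, and adjusted p = 0.12 with the GC and length trend removed. In total 9576 of 17251 genes passed, 4836 up and 4740 down, and 1842 exceeded an absolute log2 fold change of 1.

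With the plasmid for residues 245 to 255 of RB, immediate early and hypoxia genes were higher in the libraries labelled 22RV1. GADD45B, a stress sensor of the p38 and JNK pathways, rose by 2.33 ± 0.074, PPP1R15A, which restores translation after stress, by 1.69 ± 0.065, and PPFIA4, a liprin, went from 0.82 ± 0.122 to 9.04 ± 0.623 CPM. Of HIF targets and glycolytic enzymes 21 of 29 rose, 0 fell and 8 did not pass. 23 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 1.7e-19 and adjusted p = 0.018 with an estimated correlation. Members included the vasodilator peptide gene ADM (1.43 ± 0.073), BNIP3, of mitophagy (1.02 ± 0.047), and PFKFB3 (0.95 ± 0.048). PFKFB4, of the same enzyme family, rose by 1.56 ± 0.094 and PDK4, which inhibits pyruvate dehydrogenase, by 1.47 ± 0.057. Of MAPK feedback and immediate early genes 14 of 28 rose, 0 fell and 14 did not pass. 15 rose and 1 fell when adjusted over the list alone, and the list had adjusted p = 7.6e-11 and adjusted p = 0.018 with an estimated correlation. Among them were ATF3 (1.42 ± 0.051), JUN (1.04 ± 0.052) and FOS (1.34 ± 0.087). RB1 was -0.11 ± 0.049 (adjusted p = 0.24), TRIM24 -0.14 ± 0.054 (adjusted p = 0.2) and DUSP2 0.28 ± 0.114 (adjusted p = 0.21, and 0.0013 with no filter on low counts). Without EV replicate 3, DUSP2 was 0.136 (adjusted p = 0.16) and TRIM24 -0.075 (adjusted p = 0.23).

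Of dual-specificity phosphatases 4 of 19 rose, 0 fell and 15 did not pass. 5 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 0.004 and adjusted p = 0.14 with an estimated correlation. Examples were DUSP1 (0.60 ± 0.062) and DUSP10 (0.55 ± 0.065). Of ATF4 targets 12 of 39 rose, 1 fell and 26 did not pass. 16 rose and 1 fell when adjusted over the list alone, and the list had adjusted p = 2.0e-08 and adjusted p = 0.14 with an estimated correlation. Members included VEGFA (0.79 ± 0.046) and the stress transcription factor DDIT3 (0.79 ± 0.051). DDIT4, an inhibitor of mTORC1, rose by 1.07 ± 0.075. Of unfolded protein response genes 4 of 23 rose, 0 fell and 19 did not pass. 7 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 7.9e-05 and adjusted p = 0.14 with an estimated correlation. DNAJB9 was at 0.79 ± 0.052 and HERPUD1 at 0.60 ± 0.043. Of nuclear-retained transcripts 2 of 8 rose, 0 fell and 6 did not pass. 3 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 0.016 and adjusted p = 0.34 with an estimated correlation. NEAT1, the RNA of paraspeckles, was at 0.77 ± 0.085. E2F targets, genes of G2 and mitosis and heat shock genes were lower as lists. Of E2F targets 3 of 53 fell, 0 rose and 50 did not pass. 5 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 1.2e-06 and adjusted p = 0.14 with an estimated correlation. Of genes of G2 and mitosis 4 of 40 fell, 0 rose and 36 did not pass. 14 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 4.7e-07 and adjusted p = 0.34 with an estimated correlation. Of heat shock genes 1 of 17 fell, 0 rose and 16 did not pass. 1 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 0.028 and adjusted p = 0.58 with an estimated correlation. In total 667 of 17194 genes passed, 455 up and 212 down, and 1332 with no filter on low counts. EV replicate 3 stood apart from its group, with a chi-square per degree of freedom of 9.52 and 7.43 against replicates 1 and 2, which differed from each other by 3.16, and 1540 genes passed without it. The count was 257 without EV replicate 2, and 185, 189 and 186 without HA-RB(245-255) replicate 1, 2 and 3.

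At 5 µmol/L RB PROTAC, libraries labelled 22RV1 had higher sterol synthesis and amino acid stress genes and lower heat shock, replication, proteasome and luminal genes. INSIG1, a feedback regulator of sterol synthesis, rose by 1.28 ± 0.028, and CHAC1, a glutathione-degrading enzyme induced by ATF4, by 1.49 ± 0.11. Of SREBP targets 22 of 31 rose, 1 fell and 8 did not pass. 24 rose and 1 fell when adjusted over the list alone, and the list had adjusted p = 5.1e-16 and adjusted p = 0.0032 with an estimated correlation. Among them was SCD (0.45 ± 0.022). Of ATF4 targets 23 of 39 rose, 2 fell and 14 did not pass. 26 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 8.2e-13 and adjusted p = 0.0031 with an estimated correlation. Examples were ATF4 itself (0.46 ± 0.028), DDIT4 (0.81 ± 0.031) and SLC7A11 (0.72 ± 0.036). RB1 was -0.13 ± 0.045 (adjusted p = 0.074), and -0.16 (adjusted p = 0.036) without replicate 3 at 5 µmol/L. TRIM24 was 0.07 ± 0.045 (adjusted p = 0.39), 0.043 without replicate 3 at 5 µmol/L, and DUSP2 -0.11 ± 0.078 (adjusted p = 0.43), -0.068 without that library and -0.045 without replicate 2 at 0 µmol/L.

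Of heat shock genes 11 of 19 fell, 0 rose and 8 did not pass. 14 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 9.0e-11 and adjusted p = 0.0075 with an estimated correlation. Members included the chaperones HSPA8 (-0.48 ± 0.024), HSP90AA1 (-0.34 ± 0.027) and HSPH1 (-0.38 ± 0.033). Of E2F targets 29 of 53 fell, 0 rose and 24 did not pass. 35 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 3.3e-17 and adjusted p = 8.7e-04 with an estimated correlation. MCM4 was at -0.43 ± 0.036, MCM6 at -0.41 ± 0.034 and the mismatch repair gene MSH6 at -0.38 ± 0.04. Of proteasome subunits 14 of 30 fell, 0 rose and 16 did not pass. 20 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 5.7e-08 and adjusted p = 0.0075 with an estimated correlation. Examples were PSMB7 (-0.19 ± 0.036) and PSMC3 (-0.18 ± 0.034). Of luminal markers 7 of 15 fell, 0 rose and 8 did not pass. 7 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 8.7e-05 and adjusted p = 0.016 with an estimated correlation. Among them was AGR2, a protein disulfide isomerase (-0.72 ± 0.061). Of androgen receptor targets 12 of 33 fell, 5 rose and 16 did not pass. 14 fell and 5 rose when adjusted over the list alone, and the list had adjusted p = 0.0046 and adjusted p = 0.073 with an estimated correlation. TMPRSS2, a serine protease, was at -0.36 ± 0.027, the kallikrein KLK4 at -0.48 ± 0.041 and CENPN at -0.57 ± 0.035. HIF and glycolysis genes, NRF2 targets and nuclear-encoded respiratory subunits were also lower as lists. Of HIF and glycolysis genes 13 of 30 fell, 5 rose and 12 did not pass. 14 fell and 6 rose when adjusted over the list alone, and the list had adjusted p = 0.0086 and adjusted p = 0.12 with an estimated correlation. Of NRF2 targets 6 of 24 fell, 1 rose and 17 did not pass. 9 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 0.043 and adjusted p = 0.12 with an estimated correlation, and adjusted p = 0.071 with the GC and length trend removed. Of respiratory subunits 8 of 57 fell, 0 rose and 49 did not pass. 10 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 0.001 and adjusted p = 0.2 with an estimated correlation. With that trend removed, the luminal list had adjusted p = 0.053 with an estimated correlation. The lipid enzyme ACSL4 rose by 1.09 ± 0.159, while the selenoprotein SELENOW changed by -1.33 ± 0.052. In total 2303 of 19698 genes passed, 971 up and 1332 down, and 1488 without replicate 2 at 0 µmol/L.

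At 10 µmol/L, libraries labelled 22RV1 had higher sterol synthesis, amino acid stress and ribosomal protein genes and lower heat shock, replication, androgen receptor target and luminal genes. RB1 messenger RNA changed by -0.28 ± 0.045 (adjusted p = 1.4e-04), and TRIM24 was -0.03 ± 0.045 (adjusted p = 0.75), with its sign turned without replicate 3 at 0 µmol/L (0.002) or replicate 3 at 10 µmol/L (0.009). Of cytosolic ribosomal proteins 55 of 73 rose, 0 fell and 18 did not pass. 63 rose and 2 fell when adjusted over the list alone, and the list had adjusted p = 5.8e-14 and adjusted p = 0.025 with an estimated correlation. Examples were RPL15 (0.23 ± 0.025) and RPS4X (0.19 ± 0.027). Of SREBP targets 17 of 31 rose, 2 fell and 12 did not pass. 21 rose and 2 fell when adjusted over the list alone, and the list had adjusted p = 6.5e-11 and adjusted p = 0.0074 with an estimated correlation. Members included INSIG1 (1.13 ± 0.028) and FDFT1 (0.51 ± 0.031). Of ATF4 targets 22 of 39 rose, 3 fell and 14 did not pass. 24 rose and 4 fell when adjusted over the list alone, and the list had adjusted p = 2.3e-08 and adjusted p = 0.0074 with an estimated correlation. Among them were DDIT4 (0.73 ± 0.031), SLC7A11 (0.61 ± 0.036) and ATF4 (0.45 ± 0.028). CHAC1 rose by 1.28 ± 0.11, ACSL4 by 0.82 ± 0.161 and NEAT1 by 0.42 ± 0.033.

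Of heat shock genes 14 of 19 fell, 0 rose and 5 did not pass. 15 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 7.3e-12 and adjusted p = 0.0074 with an estimated correlation. HSPH1 was at -0.50 ± 0.033, HSPA8 at -0.34 ± 0.024 and HSP90AA1 at -0.33 ± 0.027. Of E2F targets 33 of 53 fell, 0 rose and 20 did not pass. 35 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 1.2e-16 and adjusted p = 9.5e-04 with an estimated correlation. Examples were MCM4 (-0.40 ± 0.035), MCM6 (-0.38 ± 0.034) and MCM10 (-0.43 ± 0.042). Of androgen receptor targets 18 of 33 fell, 2 rose and 13 did not pass. 18 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 8.8e-08 and adjusted p = 0.0074 with an estimated correlation. Examples were CENPN (-0.60 ± 0.035), the lipid phosphatase PLPP1 (-0.45 ± 0.028) and TMPRSS2 (-0.36 ± 0.027). Of luminal markers 8 of 15 fell, 1 rose and 6 did not pass. 8 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 3.7e-04 and adjusted p = 0.024 with an estimated correlation. Among them was AGR2 (-0.83 ± 0.061). Proteasome, HIF and glycolysis, NRF2 and unfolded protein response genes were lower as lists. Of proteasome subunits 11 of 30 fell, 0 rose and 19 did not pass. 14 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 5.8e-04 and adjusted p = 0.031 with an estimated correlation. Of HIF and glycolysis genes 13 of 30 fell, 2 rose and 15 did not pass. 14 fell and 3 rose when adjusted over the list alone, and the list had adjusted p = 5.8e-04 and adjusted p = 0.048 with an estimated correlation. Of NRF2 targets 7 of 24 fell, 1 rose and 16 did not pass. 8 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 0.0022 and adjusted p = 0.031 with an estimated correlation. Of unfolded protein response genes 6 of 23 fell, 1 rose and 16 did not pass. 7 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 0.036 and adjusted p = 0.083 with an estimated correlation, and adjusted p = 0.099 with the GC and length trend removed. With that trend removed, the HIF and glycolysis list had adjusted p = 0.071 and the luminal list adjusted p = 0.051 with an estimated correlation. SELENOW changed by -1.12 ± 0.052. In total 2971 genes passed, 1194 up and 1777 down. DUSP2 was -0.21 ± 0.078 (adjusted p = 0.077), and it passed without replicate 1 at 0 µmol/L (-0.26, adjusted p = 0.038) and with the GC and length trend removed (-0.25, adjusted p = 0.020).

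Between 10 and 5 µmol/L, ribosomal protein genes were higher at the higher dose, and sterol, unfolded protein response and androgen receptor target genes were lower. Of ribosomal proteins 47 of 73 rose, 0 fell and 26 did not pass. 61 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 7.6e-29 and adjusted p = 0.027 with an estimated correlation. Members included RPL10A (0.26 ± 0.028), RPL35 (0.23 ± 0.031) and RPL15 (0.17 ± 0.025). Of SREBP targets 8 of 31 fell, 0 rose and 23 did not pass. 13 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 5.9e-06 and adjusted p = 0.036 with an estimated correlation. Among them were SCD (-0.18 ± 0.022) and INSIG1 (-0.15 ± 0.027). Of unfolded protein response genes 6 of 23 fell, 1 rose and 16 did not pass. 9 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 5.4e-04 and adjusted p = 0.036 with an estimated correlation. Examples were HSPA5 (-0.28 ± 0.025) and the disulfide isomerase PDIA4 (-0.21 ± 0.028). Of androgen receptor targets 10 of 33 fell, 1 rose and 22 did not pass. 16 fell and 3 rose when adjusted over the list alone, and the list had adjusted p = 1.6e-05 and adjusted p = 0.036 with an estimated correlation. Examples were the protease ADAMTS1 (-0.24 ± 0.028) and PLPP1 (-0.23 ± 0.027). Of ATF4 targets 3 of 39 fell, 0 rose and 36 did not pass. 5 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 0.0092 and adjusted p = 0.092 with an estimated correlation. Of nuclear-encoded respiratory subunits 7 of 57 rose, 0 fell and 50 did not pass. 15 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 1.8e-06 and adjusted p = 0.092 with an estimated correlation. With the GC and length trend removed, the lists of SREBP targets (adjusted p = 0.1), the unfolded protein response (adjusted p = 0.11) and androgen receptor targets (adjusted p = 0.1) were not called with an estimated correlation. The arrestin-related ARRDC3 differed by 0.45 ± 0.05 and the lectin receptor CLEC7A by -1.22 ± 0.103, for which DESeq2 gave no adjusted p.

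In this contrast of doses 622 of 19698 genes passed, 226 up and 396 down. TRIM24 was -0.10 ± 0.043 (adjusted p = 0.28), -0.057 without replicate 3 at 10 µmol/L, and DUSP2 -0.10 ± 0.075 (adjusted p = 0.59), -0.045 without replicate 2 at 5 µmol/L. The count was 346 without replicate 1 at 5 µmol/L, 343, 247 and 365 without replicate 1, 2 and 3 at 10 µmol/L, and 949 with the GC and length trend removed, where SCD was -0.11. RB1 was -0.16 ± 0.043 (adjusted p = 0.049) and did not pass with RLE size factors (adjusted p = 0.05), with only the 6 libraries compared (adjusted p = 0.075), without replicate 2 or 3 at 5 µmol/L (adjusted p = 0.15 for both), or without replicate 1 (adjusted p = 0.25) or 2 (adjusted p = 0.15) at 10 µmol/L.

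With siRNA against RB1 in C4-2, heat shock, sterol synthesis, unfolded protein response and replication genes were lower. RB1 changed by -0.38 ± 0.056 (adjusted p = 7.4e-05) and DUSP2 by -0.35 ± 0.065 (adjusted p = 5.9e-04), from 36.9 ± 3.01 to 28.9 ± 0.383 CPM. TFRC, the transferrin receptor, went from 727 ± 24.1 to 291 ± 2.91 CPM (-1.32 ± 0.037). Of heat shock genes 14 of 18 fell, 0 rose and 4 did not pass. 14 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 6.1e-08 and adjusted p = 0.047 with an estimated correlation. Members included HSPH1 (-0.65 ± 0.04), DNAJA1 (-0.63 ± 0.038) and HSPA8 (-0.60 ± 0.033). Of SREBP targets 19 of 31 fell, 0 rose and 12 did not pass. 21 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 6.1e-08 and adjusted p = 0.047 with an estimated correlation. Among them were the cholesterol synthesis enzyme DHCR7 (-0.43 ± 0.045) and FASN (-0.39 ± 0.039). Of unfolded protein response genes 15 of 23 fell, 2 rose and 6 did not pass. 16 fell and 2 rose when adjusted over the list alone, and the list had adjusted p = 7.2e-05 and adjusted p = 0.047 with an estimated correlation. HSPA5 was at -0.53 ± 0.033.

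Of E2F targets 16 of 53 fell, 1 rose and 36 did not pass. 16 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 4.0e-04 and adjusted p = 0.047 with an estimated correlation. The flap endonuclease FEN1 was at -0.50 ± 0.044, CDC6, which loads the replicative helicase, at -0.40 ± 0.042 and the phosphatase CDC25A at -0.48 ± 0.052. With the GC and length trend removed, the heat shock, SREBP, unfolded protein response and E2F lists each had adjusted p = 0.081 with an estimated correlation, so that 0 lists were then called with it. Of proteasome subunits 21 of 28 fell, 0 rose and 7 did not pass. 22 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 4.7e-08 and adjusted p = 0.16 with an estimated correlation. Examples were PSMC4 (-0.39 ± 0.041) and PSMD3 (-0.31 ± 0.043). Of interferon-stimulated genes 5 of 30 rose, 0 fell and 25 did not pass. 4 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 0.0026 and adjusted p = 0.081 with an estimated correlation. MX1 was at 0.47 ± 0.064 and CMPK2 at 0.61 ± 0.135. Of p53 targets 11 of 26 rose, 2 fell and 13 did not pass. 11 rose and 2 fell when adjusted over the list alone, and the list had adjusted p = 0.0092 and adjusted p = 0.11 with an estimated correlation. The stress cytokine GDF15 was at 0.48 ± 0.044 and the proapoptotic BBC3 at 0.77 ± 0.111. NEAT1 rose by 0.83 ± 0.032 and the small Maf factor MAFF by 1.09 ± 0.13. In total 4056 of 15544 genes passed, 1759 up and 2297 down.

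TRIM24 was -0.12 ± 0.042 in the C4-2 RB1 knockdown (adjusted p = 0.036). It did not pass with DESeq2 (adjusted p = 0.072), with no filter on low counts (adjusted p = 0.11), without control replicate 1 (adjusted p = 0.085) or 2 (adjusted p = 0.071), or without knockdown replicate 1 (adjusted p = 0.16), 2 (adjusted p = 0.062) or 3 (adjusted p = 0.076).

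The C4-2 libraries labelled trim24si had higher oxidative stress genes and lower mitotic and replication genes than those labelled trim24nc. TRIM24 was higher in them, against the label, by 0.41 ± 0.037 (adjusted p = 5.2e-10), so every direction here is that of the label and not of TRIM24 loss. DUSP2 rose by 1.24 ± 0.035 (adjusted p = 2.8e-20) and RB1 changed by -0.34 ± 0.038 (adjusted p = 4.7e-08). Of NRF2 targets 21 of 24 rose, 0 fell and 3 did not pass. 22 rose and 0 fell when adjusted over the list alone, and the list had adjusted p = 6.9e-14 and adjusted p = 0.0084 with an estimated correlation. Members included thioredoxin reductase TXNRD1 (1.61 ± 0.022), SLC7A11 (1.33 ± 0.024) and the quinone reductase NQO1 (1.09 ± 0.021). Heme oxygenase HMOX1 rose by 2.23 ± 0.06, PTGR1, a prostaglandin reductase, by 2.58 ± 0.04, RND3 by 3.05 ± 0.079 and ATF3 by 2.21 ± 0.042. Of genes of G2 and mitosis 38 of 39 fell, 0 rose and 1 did not pass. 38 fell and 0 rose when adjusted over the list alone, and the list had adjusted p = 2.6e-21 and adjusted p = 0.0074 with an estimated correlation. Among them were HMMR (-1.09 ± 0.031), CENPF, a kinetochore protein (-0.94 ± 0.028), and ECT2, of cytokinesis (-0.80 ± 0.029). Of E2F targets 38 of 53 fell, 1 rose and 14 did not pass. 38 fell and 1 rose when adjusted over the list alone, and the list had adjusted p = 4.5e-11 and adjusted p = 0.0084 with an estimated correlation. Examples were RRM1 (-0.50 ± 0.03) and RRM2 (-0.44 ± 0.027).

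In the libraries labelled trim24si, of NF-kB targets 9 of 15 rose, 1 fell and 5 did not pass. 10 rose and 1 fell when adjusted over the list alone, and the list had adjusted p = 6.5e-04 and adjusted p = 0.073 with an estimated correlation. Members included the inhibitors NFKBIA (0.81 ± 0.031) and TNFAIP3 (1.85 ± 0.168). Of p53 targets 17 of 26 rose, 1 fell and 8 did not pass. 18 rose and 1 fell when adjusted over the list alone, and the list had adjusted p = 2.0e-05 and adjusted p = 0.073 with an estimated correlation. Members included CDKN1A, the cell cycle inhibitor p21 (0.76 ± 0.025), GADD45A (1.22 ± 0.062) and GDF15 (0.72 ± 0.025). Of SREBP targets 20 of 31 fell, 3 rose and 8 did not pass. 21 fell and 7 rose when adjusted over the list alone, and the list had adjusted p = 2.6e-04 and adjusted p = 0.11 with an estimated correlation. SQLE was at -0.88 ± 0.045 and INSIG1 at -0.55 ± 0.029. Of unfolded protein response genes 17 of 23 fell, 4 rose and 2 did not pass. 17 fell and 5 rose when adjusted over the list alone, and the list had adjusted p = 0.0021 and adjusted p = 0.22 with an estimated correlation. XBP1 was at -0.55 ± 0.026. DHRS2, a short-chain dehydrogenase, changed by -3.05 ± 0.074, the cation transporter SLC22A3 by -2.34 ± 0.149 and the laminin LAMA1 by -2.28 ± 0.143.

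Further lists moved up under the label trim24si, and nuclear-encoded respiratory subunits down. Of MAPK and immediate early genes 16 of 26 rose, 3 fell and 7 did not pass. 16 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 0.0039 and adjusted p = 0.22 with an estimated correlation. Of interferon-stimulated genes 13 of 33 rose, 3 fell and 17 did not pass. 13 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 0.038 and adjusted p = 0.19 with an estimated correlation. Of ATF4 targets 20 of 39 rose, 11 fell and 8 did not pass. 21 rose and 11 fell when adjusted over the list alone, and the list had adjusted p = 0.038 and adjusted p = 0.22 with an estimated correlation. Of proteasome subunits 18 of 28 rose, 3 fell and 7 did not pass. 18 rose and 3 fell when adjusted over the list alone, and the list had adjusted p = 0.0052 and adjusted p = 0.28 with an estimated correlation. Of nuclear-retained transcripts 6 of 8 rose, 1 fell and 1 did not pass. 6 rose and 1 fell when adjusted over the list alone, and the list had adjusted p = 0.016 and adjusted p = 0.22 with an estimated correlation. Of fibroblast markers 4 of 7 rose, 1 fell and 2 did not pass. 4 rose and 1 fell when adjusted over the list alone, and the list had adjusted p = 0.04 and adjusted p = 0.26 with an estimated correlation. Of respiratory subunits 24 of 55 fell, 5 rose and 26 did not pass. 24 fell and 6 rose when adjusted over the list alone, and the list had adjusted p = 0.025 and adjusted p = 0.24 with an estimated correlation. In total 7304 of 16939 genes passed, 3739 up and 3565 down, with 760 above an absolute log2 fold change of 1.

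The kinases, adaptors and regulators of the mTOR pathway, which the series title concerns, were called as a list in none of the 10 comparisons, with adjusted p from 0.18 (RBN plasmid, where 22 of 49 fell and 11 rose, 22 and 11 also when adjusted over the list alone) to 0.97. The lowest adjusted p was 0.16 for retinoic acid targets (RB(245-255)), 0.21 for basal epithelial markers (label trim24si) and 0.44 for neuroendocrine markers (PROTAC 5). None of these lists was called where tested. In these comparisons 1 of 10, 2 of 5 and 1 of 5 rose and 0 fell, and 2, 2 and 1 rose when adjusted over the list alone. Leukocyte markers had fewer than 5 tested members in each of the 6 tables and were not tested. Nor were basal markers in C4-2 RB1, or neuroendocrine markers with RBN and in C4-2.

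**Figure D4:**
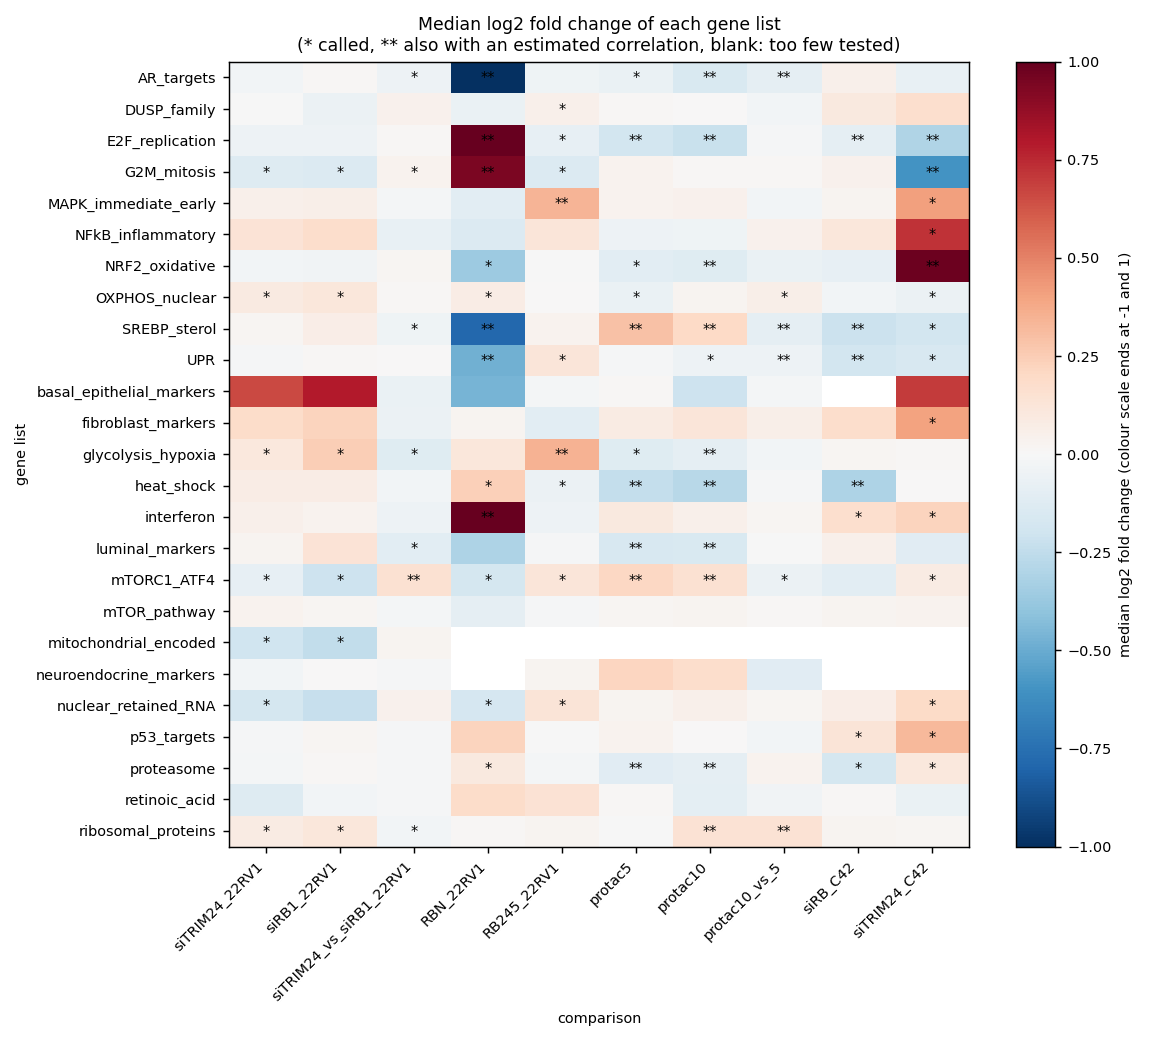
Median log2 fold change (colour) of each gene list (vertical axis) in each of the 10 comparisons (horizontal axis), with 1 asterisk for lists called at a preset correlation and a double asterisk for those also called with an estimated correlation. Of 12 lists called with the RBN plasmid, 6 carry the double asterisk, and of 11 called with PROTAC at 10 µmol/L, 10 do.

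The overlaps between comparisons were counted among genes tested in both. The siTRIM24 and siRB1 comparisons of 22RV1 shared 3322 called genes, 3320 of them in the same direction, against 354 and 244 shared rises and falls of independent lists (1932 and 1388 observed). With the GC and length trend removed they shared 836, and 836 of these had the same direction. Their fold changes correlated across genes (Pearson r 0.721, Spearman rho 0.753), with genes not independent replicates. Because the comparisons share their controls, unchanged groups were simulated 20 times and gave a median r of 0.502, with a covariance of 0.0206 against 0.0696 observed. The difference of 0.049 estimates what both share beyond gene-by-gene chance in the controls, GC trend and any other difference from siNC included. With 3 control libraries the controls could not be split, so part of the excess overlap may come from them. PROTAC at 5 and 10 µmol/L shared 1475 called genes, 1472 in the same direction, with r 0.685 against a simulated 0.575, a covariance of 0.0761 against 0.0322 and chance overlaps of 58.9 up and 120 down (545 and 927 observed).

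Between pairs of comparisons without common libraries fixed beforehand, 35.2% to 55.1% of shared genes had the same direction, while 93.5% did between PROTAC at 10 µmol/L and the C4-2 RB1 knockdown, a pair chosen after the data were seen. Of 1571 genes called in both RB1 knockdowns, 36.6% had the same direction. There 666 rose in 22RV1 and fell in C4-2, against 428 from independent lists (Fisher's exact test, p = 2.4e-41). Genes are not independent, and opposite GC trends (rho 0.613 and -0.105) were not removed. The siTRIM24 comparison of 22RV1 shared 2110 called genes with the C4-2 label trim24si, 55.1% in the same direction (r -0.017), 2676 with the RBN plasmid, 53% (r 0.012), and 177 with RB(245-255), 43.5% (r 0.021). siRB1 and PROTAC at 10 µmol/L shared 1195, 52.3% (r 0.027). RBN and RB(245-255) plasmids shared 423, 35.2% (r -0.05), and the C4-2 comparisons 2281, 54.3% (r 0.01).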

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

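Of the tests in this part, those of library scaling and of the genes shared by siTRIM24 over siRB1 with the label trim24si were chosen only after the result was seen. Under the same knockdown label, every library of one cell line moved one way and every library of the other the opposite way for 3 genes, and in each case the difference was not tested. TRIM24 was -0.57 in the siTRIM24 libraries of 22RV1 and 0.41 in the C4-2 libraries labelled trim24si. DUSP2 was 0.34 in the RB1 knockdown of 22RV1 and -0.35 in that of C4-2. Its call in 22RV1 was lost without siNC replicate 2 or 3 or siRB1 replicate 2 or 3 (adjusted p = 0.07 to 0.13). With the trend over GC content and length removed DUSP2 was 0.07 there (adjusted p = 0.80). FASN was 0.51 in the RB1 knockdown of 22RV1, 0.15 with that trend removed, and -0.39 in that of C4-2.

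The rise of TRIM24 in the C4-2 libraries labelled trim24si was not a product of TMM scaling, since its log2 ratio as a share of the raw total was 0.385. If the labels trim24si and trim24nc were exchanged, the fold changes may run against those of siTRIM24 over siRB1 in 22RV1, but their correlation across genes, which are not independent replicates, was near 0 (r = -0.047, with 15 of 31 genes called in both in the same direction). DUSP2 and RB1 ran as labelled, at 0.52 and -0.30 with siTRIM24 in 22RV1 and 1.24 and -0.34 under label trim24si. Of 2110 shared genes 1162 agreed in direction, with r again near 0 (-0.017). The siTRIM24 values may hold a difference of siNC from both knockdowns. DUSP2 was 0.27 there (adjusted p = 0.17) with the GC and length trend removed. Exchanged labels and a true rise of TRIM24 messenger RNA cannot be told apart, because the siTRIM24 over siRB1 contrast called only 54 genes and comes from another cell line. A biological rise under the siRNA was not tested.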

How the results depend on the processing

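Of the alternatives in this part, those chosen only after the data were seen were the offset for GC content and length, DESeq2 and RLE size factors for the 22RV1 tables, the limit on the fold change, and RLE and left-out libraries for the gene lists. Alternatives foreseen for FPKM values (a pseudocount of 0.1, the FPKM filter and rescaling, and the empirical Bayes fit without trend) were not run, since the tables hold counts, and no filter on low counts and RLE took their place. TRIM24 at PROTAC 10, which was not called (-0.03), ranged from -0.053 (without replicate 1 at 10 µmol/L). Its sign turned without replicate 3 at 0 µmol/L (0.002) or replicate 3 at 10 µmol/L (0.009). No other named gene kept by choice reversed under any alternative run. Of these genes, 2 calls were lost with DESeq2, 6 lost and 1 gained with the offset, and 1 lost with RLE. With no filter 2 were lost and 1 gained, and with only the 6 libraries compared 1 was lost. Over all left-out libraries 36 were lost and 2 gained, against 1556 kept on their side with the same sign.

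Called genes beyond an absolute log2 fold change of 1 numbered 76 (siTRIM24), 105 (siRB1), 4 (siTRIM24 against siRB1), 1842 (RBN), 57 (RB(245-255)), 84 (PROTAC 5), 109 (PROTAC 10), 21 (PROTAC 10 against 5), 79 (C4-2 RB1) and 760 (C4-2 label trim24si), a smaller set by construction. With the GC and length offset the counts that moved by over 1.5 times were 1244 (siTRIM24), 1806 (siRB1), 130 (siTRIM24 against siRB1) and 949 (PROTAC 10 against 5), and the cause was not tested. DESeq2 called 95 genes in siTRIM24 against siRB1, and no filter on low counts 131 there and 1332 with RB(245-255); the cause was not tested. RLE moved no count by over 1.5 times. With a correlation estimated per list, called lists numbered 0 (siTRIM24), 0 (siRB1), 1 (siTRIM24 against siRB1), 6 (RBN), 2 (RB(245-255)), 6 (PROTAC 5), 10 (PROTAC 10), 4 (PROTAC 10 against 5), 4 (C4-2 RB1) and 3 (C4-2 label trim24si). At adjusted p under 0.01 the shared called genes were 1805 (siTRIM24 and siRB1), 772 (PROTAC 5 and 10), 670 (both RB1 knockdowns), 972 (siTRIM24 and label trim24si), 511 (siRB1 and PROTAC 10), 1370 (siTRIM24 and RBN), 32 (siTRIM24 and RB(245-255)), 118 (RBN and RB(245-255)) and 1171 (both C4-2 comparisons).

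Leaving out 1 library at a time gave 2339 (without siNC replicate 2; 2593 without siNC replicate 3 and 2517 without siTRIM24 replicate 2) to 4278 called genes for siTRIM24, 3609 to 5429 for siRB1, 27 (without siRB1 replicate 2; 35 without siRB1 replicate 3 and 32 without siTRIM24 replicate 1) to 51 for siTRIM24 against siRB1, 9028 to 9222 for RBN, 185 (without HA-RB(245-255) replicate 1; 189 and 186 without replicate 2 and 3, and 257 without EV replicate 2) to 1540 (without EV replicate 3) for RB(245-255), 1488 (without replicate 2 at 0 µmol/L) to 2140 for PROTAC 5, 2051 to 2638 for PROTAC 10, 247 (without replicate 2 at 10 µmol/L; 343 and 365 without replicate 1 and 3, and 346 without replicate 1 at 5 µmol/L) to 598 for PROTAC 10 against 5, 2942 to 4705 for C4-2 RB1 and 6451 to 6777 for the label trim24si. Called lists ranged from 3 (without siTRIM24 replicate 3; 4 without siRB1 replicate 3 and 4 without siTRIM24 replicate 1) to 8 in siTRIM24 against siRB1. RB1 at PROTAC 5 ranged from -0.093 to -0.155 (without replicate 3 at 5 µmol/L). The shallowest library, PROTAC 0 replicate 1 with 9505662 counts, limits the low genes of its table.

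Groups shared replicate numbers, but libraries with the same number did not deviate together (correlations from -0.091 to 0.044, with 0 of the pairs over 0.1), so the numbers were not taken as pairs. With the number as a replicate block, PROTAC 10 against 5 called 936 genes, siTRIM24 against siRB1 called 4 lists, RB1 at PROTAC 5 was -0.12 (adjusted p = 0.043) and TRIM24 in the C4-2 RB1 knockdown had adjusted p = 0.1. Lists that lost their call with the block were G2 and mitosis (adjusted p = 0.082), ribosomal proteins (adjusted p = 0.09) and SREBP targets (adjusted p = 0.085) in siTRIM24 against siRB1, nuclear-retained transcripts with siTRIM24 (adjusted p = 0.07), the proteasome with RBN (adjusted p = 0.077), heat shock with RB(245-255) (adjusted p = 0.053) and ATF4 targets with the label trim24si (adjusted p = 0.081). No other count moved by over 1.5 times and no other kept gene changed its side.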

Other observations

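Of the tests in this part, those of cell line identity and of table counting, of a common difference from the controls, the overlaps of PROTAC with C4-2 RB1 knockdown, of PROTAC with RBN and of RBN with C4-2 RB1 knockdown, and the covariance bound for GC content were chosen only after the result was seen. PROTAC at 10 µmol/L in libraries labelled 22RV1 and RB1 knockdown in C4-2 shared 1452 called genes, of which 1358 (93.5%) had the same direction, 428 up and 930 down, against 120 and 286 from independent lists (Pearson r 0.379 and Spearman rho 0.456 across genes, which are not independent replicates). Heat shock, replication and proteasome genes were lower in both, with HSPA8 at -0.34 with PROTAC and -0.60 in C4-2 and HSPH1 at -0.50 and -0.65, and NEAT1 was higher in both, at 0.42 and 0.83. In C4-2 the proteasome list had adjusted p = 0.16 with an estimated correlation, and the heat shock and replication lists had adjusted p = 0.081 with it once the GC and length trend was removed. SREBP targets went apart, where 17 of 31 rose with PROTAC and 19 of 31 fell in C4-2, a difference that was not tested. The PROTAC and RBN comparisons shared 2193 called genes, 38.8% in the same direction, and RBN and C4-2 RB1 knockdown shared 2852, 34.4% in the same direction.

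RBN and PROTAC libraries, labelled 22RV1, resembled C4-2 libraries. At most 4.5% of the genes found only in the 22RV1 siRNA controls were detected in any of them, and the Spearman rho across genes with the C4-2 RB1 controls was 0.972 for the RBN controls and 0.984 for PROTAC at 0 µmol/L, against 0.874 and 0.885 with siNC. A difference in annotation or counting between tables is argued against only as the whole cause. RB(245-255) controls, counted under C4-2 names, correlated better with siNC (0.949) than with C4-2 controls (0.908 and 0.909). RBN and PROTAC libraries may come from C4-2 or a related line, a hypothesis found and tested on the same data. The RB(245-255) libraries detected 66.3% to 67.3% of the 22RV1 genes and 15.6% to 20% of the C4-2 genes, short of siNC, and why was not tested. BDP1, of the 22RV1 genes, had 236.6 CPM in siNC and 0.025 in their controls, so counting may enter the sets.

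The siTRIM24 and siRB1 libraries of 22RV1 moved together against siNC. Chance values of the shared controls are argued against as the whole cause (covariance of 0.0696 against at most 0.0226 in simulations). Of genes called in both RB1 knockdowns 36.6% agreed in direction. With opposite GC trends not removed, a common response to RB1 loss cannot be judged. A trend over GC content and length is argued against only as the whole cause, as the covariance was 0.0446 after its removal; the bound set beforehand, a correlation above 0.5, was met at 0.625 but shared controls alone gave 0.502. A difference of the siNC libraries from both knockdowns that depends on neither target cannot be told apart from a shared response, because 99.5% of genes called with siTRIM24 had the same sign with siRB1 and the design has no second control.

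Each comparison's 6 libraries split into 3 and 3 in 10 ways, too few for a share under 0.05. In each, 1 of 10 splits, the real one, reached the real count. The real split and the highest other called 3843 and 1 (siTRIM24), 5246 and 0 (siRB1), 50 and 6 (siTRIM24 against siRB1), 9576 and 1 (RBN), 667 and 2 (RB(245-255)), 2009 and 2 (PROTAC 5), 3157 and 0 (PROTAC 10), 538 and 7 (PROTAC 10 against 5), 4056 and 0 (C4-2 RB1) and 7304 and 0 (C4-2 label trim24si).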
